A study of Homo sapiens with 4 samples.

How the data were processed

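Total RNA from HEK293 cells, an established human embryonic kidney cell line, was measured on 4 single-colour Affymetrix expression arrays, 2 from cells kept for 7 days in medium with 450 mg/dl glucose (high glucose) and 2 from cells kept for 7 days in medium with 100 mg/dl glucose (low glucose). Biotin-labelled cRNA was hybridised, per the labels' protocols. Per the labels, each array is a biological replicate. The groups share the replicate numbers 1 and 2, but no label says that a number marks a shared batch or day.

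The values are signal intensities on a linear scale, 1 per probe set and array, as deposited by the authors. The submitters' processing notes name GCOS, the Affymetrix array software, without a version. Further steps of the authors' processing are not given in the sources used here. Tested on the values, the 2% trimmed mean of each array lay at about 200.02 signal units, so the intensities deposited by the authors had already been scaled to a common trimmed mean. Such scaling sets the overall level of the 4 arrays equal, so a change shared by most transcripts cannot be seen in it. Detection calls were not used here, and low signals carry no statement of presence or absence. The number of arrays limits the precision, and no counting error applies.

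The table held 54675 probe sets, of which 62 were control probe sets. GEO's platform annotation gave exactly 1 gene for 41097 probe sets, several genes for 1801 and none for 11777, and only probe sets with 1 gene were named. Of these, 41043 were matched by gene identifier in the RefSeq gene table of GRCh38.p14, which served for symbols and for the order of neighbouring genes only. No coordinates are given, because the deposited values name no genome build. Certain list members had no probe set that names 1 gene, and these were not analysed here.

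Signals were log2-transformed without a pseudocount and without further normalization. The 62 control probe sets were left out. The remaining probe sets were kept when their mean log2 signal over the 4 arrays was at or above the median, equal to a signal of 32.9, which left 27307. Each gene was represented by its probe set with the highest mean signal, giving 12242 genes. High and low glucose were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, over all 4 arrays and with no covariate. P-values are two-sided and were adjusted by the Benjamini-Hochberg method. An adjusted p under 0.05 was the threshold. Every adjusted p of a gene given below comes from this limma fit, and every fold change is high against low glucose on the log2 signal scale. Errors beside log2 fold changes are standard errors from the fit, and errors beside signals are SDs over n = 2 arrays.

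Before the data were examined, 26 pathway lists and 6 lists of cell type markers were fixed from textbook knowledge, together with the test, the alternatives and the rule for naming genes. Lists with 5 or more measured members were tested with limma's camera, with a preset inter-gene correlation of 0.01. This test asks whether a list moved against all other measured genes. Adjusted p-values of lists were taken over the 29 lists tested. With the correlation estimated from the residuals, camera works with the few residual degrees of freedom of 4 arrays, and its adjusted p is given beside each list called. limma's fry, which tests whether the members of a list move on balance one way without setting them against other genes, was run beside it. The rule named the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose arrays did not overlap between groups. It also named up to 4 members of each list with the smallest p, and TXNIP and ARRDC4 whatever their values. ASNS, SLC7A5, ATF5, HSPA5, SC5D, FASN, ACLY, CDK1, TOP2A, HSPB1, DNAJB1, TGFB1, COL4A2, TIMP1 and SLC2A1 fall outside this rule and were chosen after their values had been seen, as were the genes named from lists added later. Scaling to the poly-A spikes was not run, because the amount added is not given in the sources used here. Instead, genes that rose by more than the median spike difference were counted.

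The gene test and the list test were tested on simulated data built from the means and spread of these 12242 genes, with 200 genes changed. For the comparison of high and low glucose, the gene test recovered 40.0% of genes changed by 0.5 log2 units, 69.6% of those changed by 1 and 93.9% of those changed by 2. On average 4.77% of its calls were false. The list test called the 1 planted list and 0 of 31 unchanged lists. Simulated genes varied independently of each other, with no batch, and few were changed, while 57.6% were called in the data. These rates may therefore not hold for the data, and the list result does not cover lists whose members are correlated.

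Alternatives covered normalization between arrays (quantile, median centring, cyclic loess), the filter on dim probe sets, a pseudocount of 9.57 signal units, the settings of eBayes, the choice of probe sets, the replicate number as a block, and leaving out each array in turn. Scripts used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.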

Results

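Gene expression was profiled in HEK293 cells that had spent 7 days in medium with high glucose, at 450 mg/dl, and in cells given 100 mg/dl for as long, with 2 arrays per condition. The comparison asks which transcripts differ in level between these glucose concentrations. The trimmed mean signal was 200.02 on each array, and the median signal ranged from 33.3 to 38.7. Across the 12242 measured genes, replicate arrays correlated with r = 0.990 in high glucose and r = 0.989 in low glucose, and arrays of different groups with r between 0.928 and 0.931. These correlations are across genes, which are not independent replicates. The labels call the arrays biological replicates without saying how the cultures were kept apart. The p-values set each group difference against the spread within the groups of these samples, which eBayes moderates with that of other genes.

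Members of the ATF4 and amino acid response and of the ER chaperone lists were lower in high glucose in 26 of 28 and 19 of 19 measured genes, with list medians of -1.52 and -1.28 log2 units (both camera adjusted p = 0.31 with an estimated correlation). The largest of these differences were in single genes. DDIT3, GDF15, NUPR1 and TRIB3, all induced in the integrated stress response, were 14.5-fold to 48.5-fold lower in high glucose. CCN2, CCN1 and THBS1 were 63.2-fold, 6.20-fold and 9.67-fold higher in high glucose, within an extracellular matrix and TGF-beta list of which 9 of 20 members rose and 4 fell (camera adjusted p = 0.32 with an estimated correlation). Of the 12242 genes, 7049 (57.6%) differed, with 2970 higher and 4079 lower in high glucose (limma, adjusted p under the threshold). A change of at least 1.5-fold was found for 1325 of the higher and 2358 of the lower genes, and a change of at least 4-fold for 39 and 133.

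The share of higher genes among the calls was 42.1% with the authors' scaling and 58.8% (4052 of 6887) after median centring, which moved the median of all genes from -0.10 to 0.07 on the log2 scale. Small changes therefore have no settled direction, and changes are best read against this median. Certain control probe sets also differed by group. The 24 probe sets for the bacterial poly-A transcripts that are added to RNA before labelling were higher on both high glucose arrays than on either low glucose array, by a median of 1.94 log2 units or 3.84-fold. Of the 12242 genes, 42 rose by more than this median spike difference, against 2970 called higher. Set against the spikes, every smaller rise would turn into a fall. The 6 probe sets for ribosomal RNA were higher by a median of 1.73 log2 units, and 5 of them separated the groups. The 18 hybridisation control probe sets had medians of 874 on high glucose replicate 2, 867 and 886 on the low glucose arrays, and 485 on high glucose replicate 1. Ratios of 3′ to 5′ signal lay between 1.03 and 1.23 for GAPDH and between 1.17 and 1.36 for ACTB. The labels name no labelling batch, and any batch that follows these controls cannot be told apart from glucose in the gene results below.

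**Figure D1:**
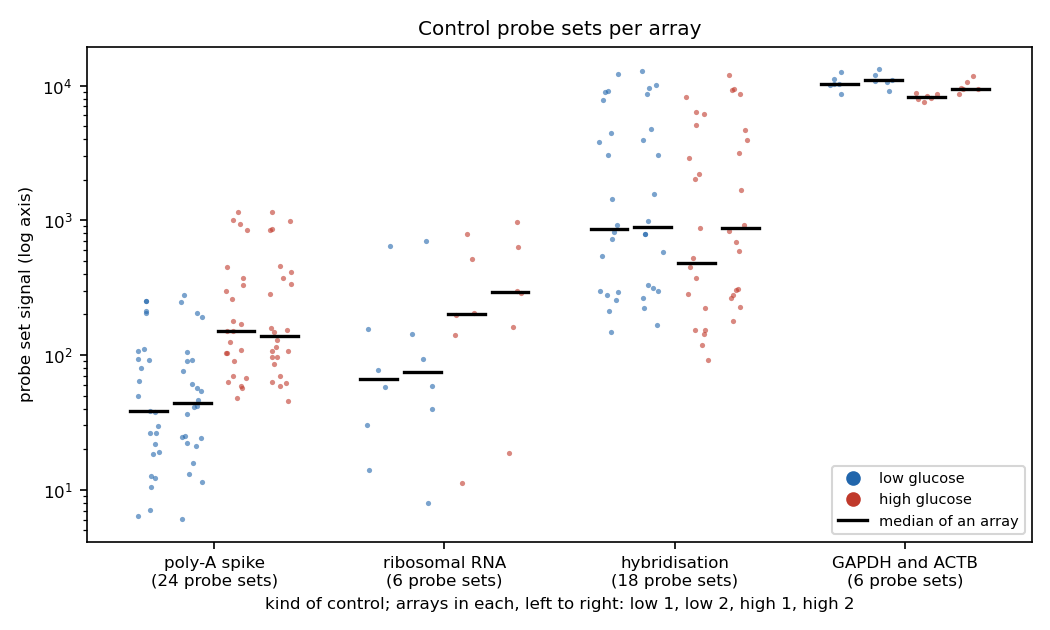
Signal (log axis) of each control probe set on each array, by kind of control, with the median of each array as a bar. Poly-A spike medians were 38.1 and 44.0 on the low glucose arrays and 151 and 139 on the high glucose arrays, while GAPDH and ACTB medians lay between 8229 and 10940.

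The largest rises in high glucose were led by HBE1, epsilon globin, at 2808 ± 28 signal units against 5.26 ± 1.5 in low glucose. This rests on 1 probe set. The other HBE1 probe set was below the filter, with 16.2 and 29.4 in high glucose and 60.2 and 24.1 in low glucose. CCN2, a secreted matricellular protein, rose 63.2-fold (5.98 ± 0.13 log2 units, adjusted p = 3.8e-07), from 51.0 ± 10.6 to 3187 ± 53. ANKRD1, a cardiac and muscle ankyrin repeat protein, rose 20.3-fold, GLIPR1 21.1-fold and MYOF, a membrane repair protein, 18.9-fold. EIF5A, a translation factor, rose by 4.25 ± 0.08 log2 units in its brightest probe set, from 89.7 ± 0.3 to 1709 ± 7. Its other measured probe sets rose by 2.29 ± 0.21 log2 units in one case and stood at 0.46 ± 0.22 without passing the test in the other. The remaining genes of the 12 were THBS1 (9.67-fold), TFPI2 (9.32-fold), COL9A3 (9.25-fold), TRIM58 (8.55-fold), CLDN10 (7.88-fold) and SYTL5 (7.46-fold). For HBE1, THBS1, ANKRD1, GLIPR1, COL9A3, TRIM58 and CLDN10 the low glucose mean lay below the filter signal of 32.9, a level not shown to be above background.

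The largest falls in high glucose were GDF15, a stress-induced cytokine, from 2084 ± 32 in low glucose to 44.0 ± 13.7 (48.5-fold, adjusted p = 1.4e-06), and NUPR1, a stress-induced chromatin protein, from 1089 ± 53 to 27.4 ± 11.8 (41.7-fold). KLHDC7B fell 40.8-fold and DNAH17, an axonemal dynein, 35.9-fold. SPATA24 fell 29.7-fold in its brightest probe set, from 7239 ± 469 to 247 ± 62. Its other probe set had a log2 difference of 0.17 ± 0.19 and did not pass. DDIT3, the transcription factor CHOP, fell 23.0-fold and TRIB3, a pseudokinase induced with it, 14.5-fold. HRK, a pro-apoptotic BH3-only gene, fell 19.8-fold in high glucose. The others were SH3BGR (17.1-fold), CLSTN2 (16.6-fold), BEST1 (13.7-fold) and CYP4X1 (13.6-fold). In NUPR1, KLHDC7B, DNAH17, CLSTN2 and CYP4X1 the high glucose mean was below 32.9.

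Genes of the ATF4 and amino acid response, which is switched on by nutrient and ER stress, were lower in high glucose nearly throughout. Of 28 measured members, 26 fell, 1 rose and 1 did not pass, and the counts adjusted over the list alone were also 26 and 1. CEBPB fell from 5420 ± 113 in low to 910 ± 39 in high glucose (5.95-fold), SLC3A2 5.17-fold, SLC7A11 8.06-fold and asparagine synthetase, ASNS, 3.29-fold. The member that rose was SLC7A5, the light chain partner of SLC3A2 in amino acid transport, by 0.80 log2 units, and ATF5 stood at -0.14. The list median was -1.52 log2 units, and the list was shifted down against other genes (camera adjusted p = 5.3e-11, adjusted p = 0.31 with an estimated correlation). With an estimated correlation camera called 0 of the 29 lists, 4 of them at an unadjusted p under 0.05. Calls by fry numbered 22, but fry does not set a list against other genes, and 57.6% of all genes were called. The same arrays differ 3.84-fold in the poly-A spikes, in the opposite direction.

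ER chaperones and unfolded protein response genes fell in high glucose in all 19 members measured, with 19 also past the threshold adjusted over the list alone. HERPUD1, which acts in ER-associated degradation, fell 6.47-fold (4078 ± 119 to 630 ± 17), HYOU1 5.68-fold, DNAJB9 5.33-fold and the transcription factor XBP1 4.54-fold. HSPA5, the main ER chaperone BiP, fell by 1.28 log2 units. The list median was -1.28 and its shift had an adjusted p of 3.5e-10 (adjusted p = 0.31 with an estimated correlation).

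Cholesterol synthesis and uptake genes were lower in high glucose in 16 of 17 members, in both adjustments, with SC5D at -0.03 and not passing. INSIG1, the sterol-regulated retention protein, fell 6.98-fold (2854 ± 62 to 414 ± 93), SREBF2, the transcription factor of the pathway, 4.32-fold in its brightest probe set, LSS 3.33-fold and SQLE 2.94-fold. The other SREBF2 probe sets fell by less, with log2 differences of -0.98 and -0.34, and the last did not pass. The list was shifted down (median -0.98, camera adjusted p = 6.9e-07, adjusted p = 0.31 with an estimated correlation). In fatty acid synthesis, 8 of 13 members fell and 2 rose, with the same counts adjusted over the list alone. FADS2 fell 3.90-fold, SCD 2.71-fold and ACSS2 2.45-fold, and SREBF1, a further transcription factor of lipid synthesis, fell by 2.00 log2 units, while FASN (0.06) and ACLY (-0.10) did not pass. That list missed the threshold (camera adjusted p = 0.053) and passed after each of the 3 normalizations (adjusted p = 0.040, 0.040 and 0.044), with no filter (0.017), with the stricter filter (0.048), with the replicate block (0.044) and without high glucose replicate 1 (0.032), with a range of 0.017 to 0.44 over all alternatives.

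**Figure D2:**
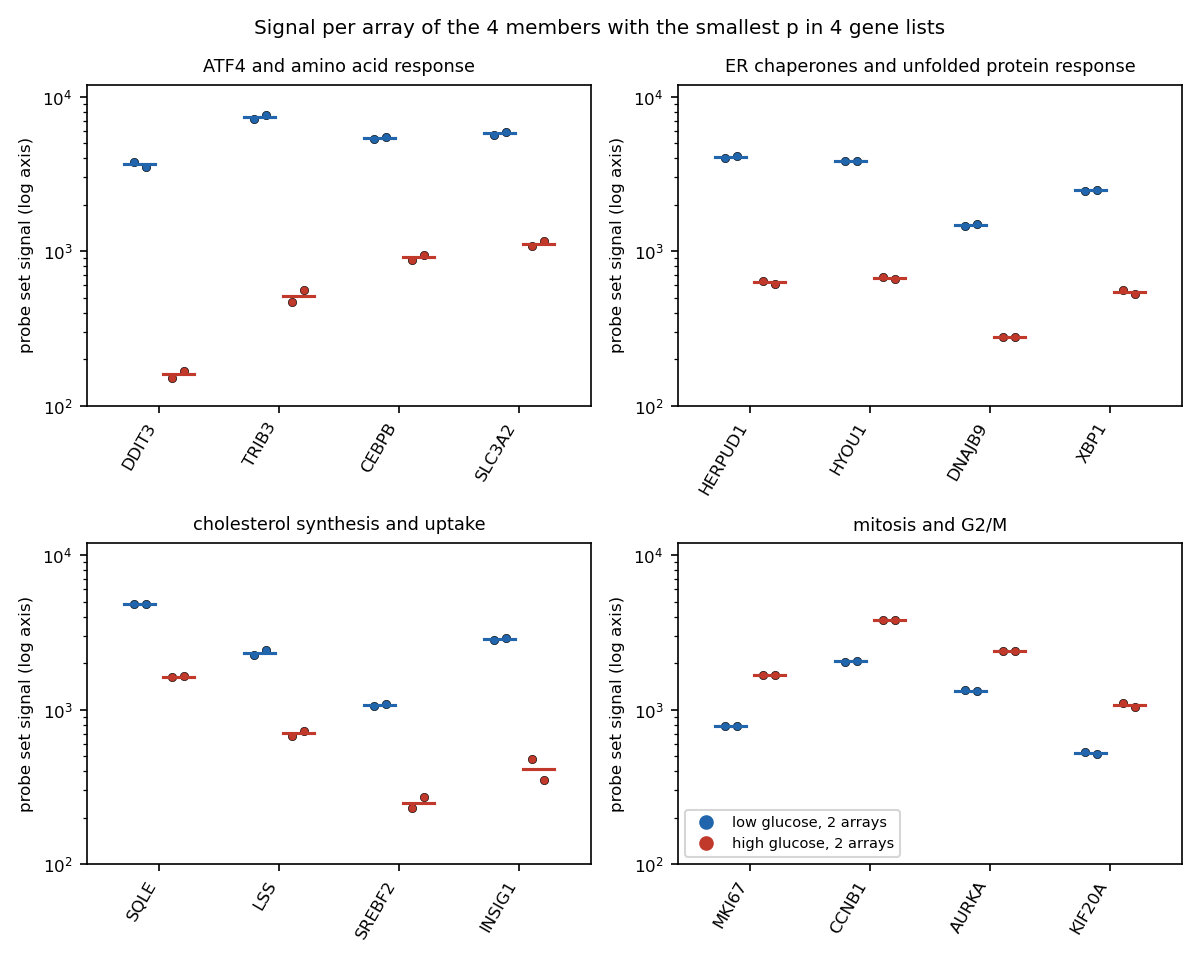
Probe set signal (log axis) on each array, with the group mean as a bar, for the 4 members with the smallest p in each of 4 lists. Low glucose arrays lie above high glucose arrays for the ATF4, ER and cholesterol genes, and below them for MKI67, CCNB1, AURKA and KIF20A.

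Mitotic genes were moderately higher in high glucose. The poly-A spikes (3.84-fold) and ribosomal RNA probe sets (3.31-fold) rose by more than any mitotic gene named here. Of 25 members, 19 rose and 0 fell, in both adjustments. MKI67, the proliferation marker Ki-67, rose 2.14-fold in its brightest probe set (782 ± 5 to 1671 ± 6). Its other probe sets stood at 0.61, 0.25 and 0.05 log2 units, and the last did not pass. CCNB1 rose 1.84-fold, AURKA 1.80-fold and KIF20A 2.03-fold, while CDK1 (0.01) and TOP2A (0.12) did not pass. A further probe set of CCNB1 rose by 0.38 log2 units and a further probe set of AURKA by 0.77. Another probe set of TOP2A was called in the opposite direction. The list was shifted up (median 0.49, camera adjusted p = 7.5e-08, adjusted p = 0.31 with an estimated correlation). DNA replication genes were also shifted up (median 0.13, adjusted p = 0.012, adjusted p = 0.32 with an estimated correlation), with 10 of 24 rising and 2 falling in both adjustments. GINS2, RRM2 and GINS1 rose 1.64-fold, 1.68-fold and 1.64-fold. CDT1, a replication licensing factor, fell 2.66-fold. Without _x_at and _s_at probe sets GINS2 stood at 0.02 and did not pass.

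Cytosolic heat shock genes were shifted up in high glucose (median 0.43, camera adjusted p = 0.0035, adjusted p = 0.32 with an estimated correlation), with 7 of 12 members rising and 2 falling, and 8 and 2 adjusted over the list alone. HSPA4 rose 3.47-fold (756 ± 3 to 2620 ± 21), HSPE1, the mitochondrial co-chaperonin, 3.10-fold, CHORDC1 2.92-fold and HSPH1 2.63-fold. HSPB1 fell by 0.37 log2 units and DNAJB1 fell by 0.26 log2 units, and after median centring no member was called lower. The poly-A spikes were 3.84-fold higher on the same arrays, a larger rise than that of any heat shock gene named here.

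Transcripts of 3 lists of mitochondrial metabolism genes were shifted up, in the same direction as the 3.84-fold difference of the poly-A spikes but by less. In the TCA cycle and pyruvate dehydrogenase list 10 of 17 members rose and 3 fell (median 0.31, camera adjusted p = 0.0043, adjusted p = 0.32 with an estimated correlation). DLAT and PDHB, subunits of pyruvate dehydrogenase, rose 1.84-fold and 1.75-fold, DLST 1.63-fold and IDH3A 1.57-fold. In fatty acid oxidation and ketone metabolism 10 of 17 rose and 3 fell (median 0.46, adjusted p = 0.014, adjusted p = 0.32 with an estimated correlation). CPT2 rose 2.27-fold, ETFA 1.68-fold and ECI2 1.37-fold, and ECI1 fell 2.10-fold. In oxidative phosphorylation 14 of 32 rose and 6 fell (median 0.13, adjusted p = 0.019, adjusted p = 0.58 with an estimated correlation), among them NDUFV2 (2.27-fold higher), NDUFC1 (2.12-fold) and NDUFB3 (1.65-fold). Counts adjusted over each list alone were the same in these 3 lists. The oxidative phosphorylation shift lost its call without high glucose replicate 2 (adjusted p = 0.051), without low glucose replicate 1 (0.059), with the stricter filter (0.058) and without _x_at and _s_at probe sets (0.060), with a range of 0.0021 to 0.060 over all alternatives.

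Genes of the extracellular matrix and TGF-beta response went both ways, with 9 of 20 rising, 4 falling and 7 not passing, and with 10 and 4 adjusted over the list alone. Beside CCN2 and THBS1, CCN1 rose 6.20-fold (510 ± 46 to 3155 ± 10), TGFB1 1.94-fold and fibronectin, FN1, 1.92-fold. TIMP3, a metalloproteinase inhibitor, fell 3.73-fold. COL4A2 and TIMP1 had log2 differences of 0.16 and 0.09 and did not pass. The poly-A spikes differed in the direction of the rises, 3.84-fold. The list median was 0.31 and its mean 0.77 (camera adjusted p = 0.0062, adjusted p = 0.32 with an estimated correlation).

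Ribosomal protein genes, among the brightest on the arrays, were lower in high glucose in 16 of 17 members, in both adjustments. RPL3 fell 1.72-fold and RPL18 1.61-fold. Of 2 further RPL18 probe sets, 1 went the opposite way, at 0.28 log2 units, and did not pass. The list median was -0.49 (camera adjusted p = 0.0035, adjusted p = 0.58 with an estimated correlation). Its mean shift against other genes was -0.371, and turned to 0.031 with quantile normalization. After quantile normalization the median was -0.03, 5 members fell and the list was not called (adjusted p = 0.49, the highest of its alternatives, which began at 7.0e-07). After median centring 7 members fell, and without low glucose replicate 1 or 2, 8 or 4 members fell.

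The NF-kappaB and inflammation list fell in 5 of 8 members and rose in 0, in both adjustments (median -0.75, camera adjusted p = 0.035, adjusted p = 0.32 with an estimated correlation). CXCL8, the chemokine interleukin-8, fell 8.97-fold to 23.4 ± 6.7, a mean below the filter signal of 32.9, RELB 3.18-fold, NFKB1 1.72-fold and NFKBIA 1.65-fold. The list lost its call without low glucose replicate 1 (adjusted p = 0.059, alternatives from 0.0073). Interferon response genes fell in 10 of 14 members and rose in 1, with IRF1 2.61-fold, IRF9 2.78-fold, IRF7 2.09-fold and IFITM3 1.52-fold lower. This list did not pass (adjusted p = 0.053) and passed after median centring (adjusted p = 0.018), with no filter (0.017), with no trend (0.044) and with the mean of probe sets (0.035), with a range of 0.017 to 0.36 over all alternatives.

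Among genes of glucose handling, TXNIP, a thioredoxin-binding protein induced by glucose through MondoA, rose 2.24-fold (112 ± 21 to 249 ± 3, adjusted p = 6.0e-04), and its other 2 probe sets rose by 1.65 and 2.53 log2 units. ARRDC4, its paralog, rose 2.03-fold (160 ± 5 to 324 ± 19). BHLHE40 fell 2.61-fold and RGS16 4.97-fold, so that of 8 measured MondoA and ChREBP targets 4 rose and 3 fell, and the list was not shifted (adjusted p = 0.65), with its median at 0.15, its mean at -0.25, and the direction up by camera and down by fry. Of 17 glycolytic enzymes 8 rose and 4 fell (median 0.12, adjusted p = 0.17). GPI and PFKP each rose 1.57-fold, PKM 1.34-fold, and ENO2, the neuronal enolase, fell 2.22-fold. After quantile normalization this list was called up (adjusted p = 0.0039), as it was without high glucose replicate 1 (adjusted p = 0.040), with a range of 0.0039 to 0.50 over all alternatives. Among transporters and regulators of glycolysis, 5 of 16 rose and 4 fell, with TIGAR higher by 1.32 log2 units, SLC2A3 (GLUT3) 2.13-fold and SLC2A6 1.61-fold higher and SLC2A10 1.99-fold lower. SLC2A1 (GLUT1) stood at 0.23 and did not pass, and that list was not called (adjusted p = 0.38).

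In the pentose phosphate list 4 of 9 members rose and 3 fell (adjusted p = 0.53). ME1, the cytosolic malic enzyme, rose 2.28-fold, and PGLS and PGD fell 2.00-fold and 1.69-fold. For TKT the 2 brighter probe sets fell (the brightest by 0.72 log2 units) and the dimmest rose by 1.22, and 1 further probe set of PGLS was also called in the opposite direction. In the hexosamine list 3 of 11 rose and 6 fell (adjusted p = 0.38), with OGA, which removes O-GlcNAc, 2.08-fold higher, GNPNAT1 1.69-fold higher, PMM1 1.98-fold lower and NANS 1.56-fold lower. The polyol and osmotic list (1 of 6 rose, 3 fell, adjusted p = 0.53) was led by SLC38A2, 2.08-fold lower, and HSPA4L, 1.96-fold higher.

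Other lists without a call in the main setting still held single large changes. VEGFA fell 5.55-fold (2316 ± 132 to 417 ± 12), P4HA2 4.15-fold and NDRG1 1.98-fold, while ADM rose 2.30-fold, so that 8 of 16 hypoxia genes fell and 3 rose (adjusted p = 0.17). Of 19 NRF2 and antioxidant genes 10 rose and 5 fell (adjusted p = 0.17), with HMOX1, heme oxygenase, 4.84-fold lower and GPX1 and TXNRD1 2.12-fold and 1.86-fold higher. Lysosome and autophagy genes fell in 12 of 20 members and rose in 5 (adjusted p = 0.10), led by WIPI1, 3.14-fold lower, and MCOLN1, 2.37-fold lower. That list passed after quantile normalization (adjusted p = 0.041) and without _x_at and _s_at probe sets (0.049), with a range of 0.041 to 0.15 over all alternatives. Insulin signalling and FOXO genes fell in 10 of 17 members and rose in 1 (adjusted p = 0.066), with IRS2, IGFBP2 and FOXO3 1.96-fold, 1.86-fold and 1.83-fold lower. This list was called down with no filter (adjusted p = 0.027), the stricter filter (0.025), no _x_at and _s_at probe sets (0.0039), and without high glucose replicate 1 (0.044) or low glucose replicate 2 (0.049), with a range of 0.0039 to 0.11 over all alternatives. Immediate early genes were split, with 6 of 17 rising and 4 falling, at a camera adjusted p of 0.45. IER3 (2.73-fold) and DUSP1 (2.26-fold) were among the rises, and JUN (2.22-fold) and KLF6 (1.89-fold) among the falls. Of 2 further DUSP1 probe sets, 1 went the opposite way, at -0.49 log2 units, and did not pass. In the renin-angiotensin list VEGFA fell, LGALS3 rose 1.37-fold, and 3 of 5 did not pass (adjusted p = 0.53). ATP6AP2 in that list stood at -0.11, did not pass, and changed sign after median centring (0.063).

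**Figure D3:**
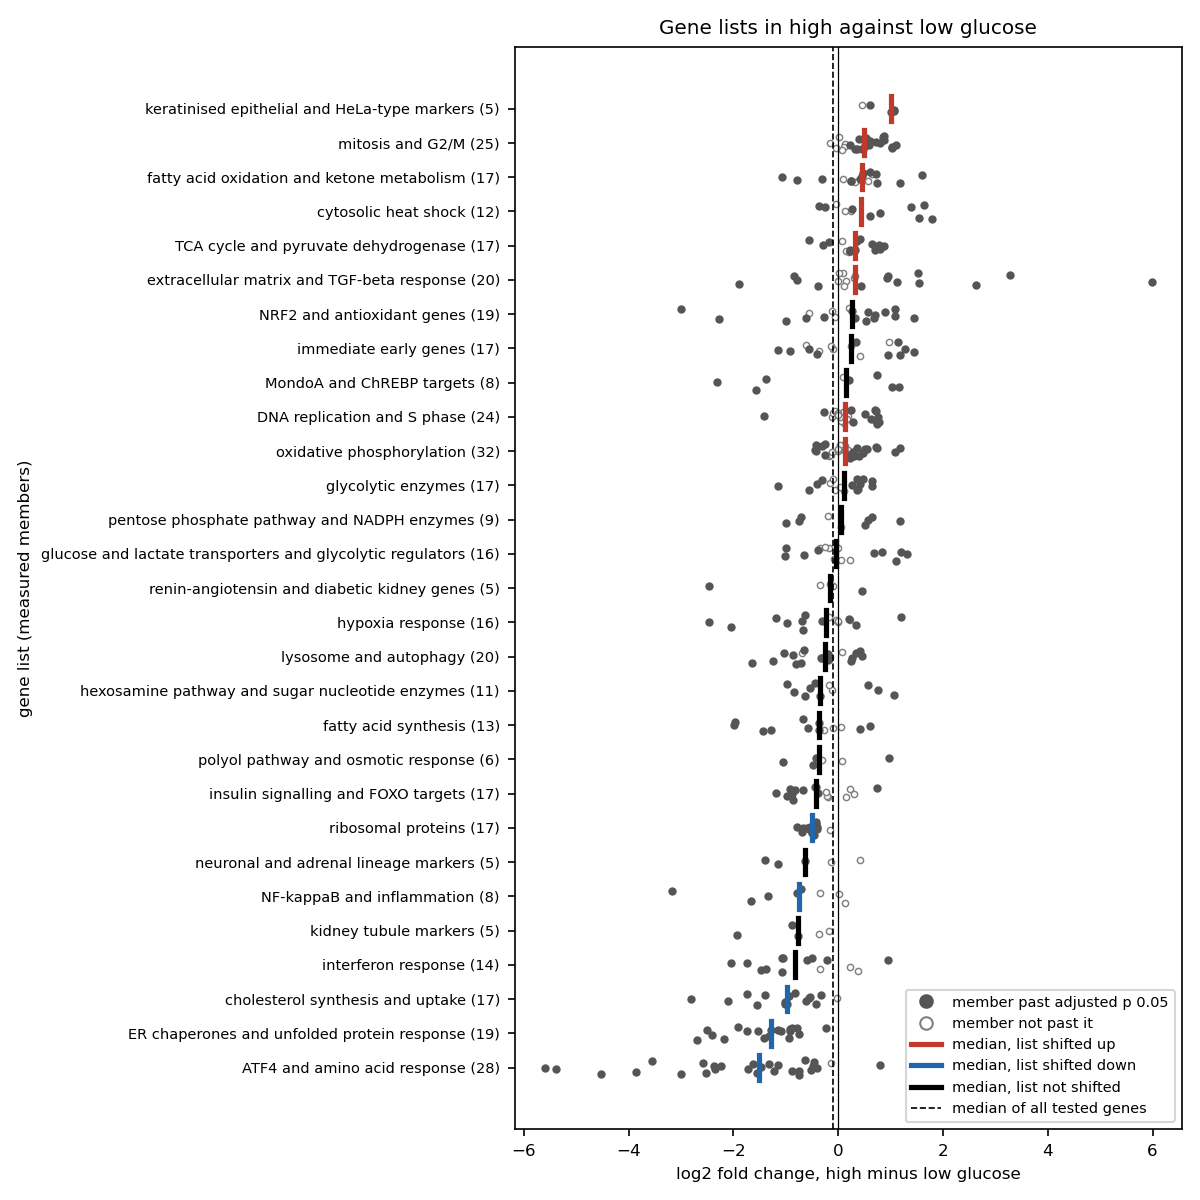
Log2 fold change, high minus low glucose, of every measured member of the 29 lists tested, with filled points for members past adjusted p 0.05 and a bar at the list median, coloured where the list was called. The ATF4, ER and cholesterol lists lie furthest down, with medians of -1.52, -1.28 and -0.98, against -0.10 for all genes (dashed line).

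Among cell type markers, the list of keratinised epithelial and HeLa-type markers rose in 4 of 5 measured members in both adjustments. The list was fixed with 11 members, of which 9 had a probe set that names 1 gene and 5 were measured. Its median was 1.01 (camera adjusted p = 0.0039, adjusted p = 0.32 with an estimated correlation). KRT8 was 2.09-fold, KRT18 2.10-fold, SFN 2.01-fold and KRT19 1.52-fold higher in high glucose. KRT5, KRT6A, KRT14 and KRT17, which the list also held, were not among the members that rose, so the rise does not cover them. KRT8 and KRT18 were also bright on the low glucose arrays, at 2871 ± 37 and 4301 ± 11. The poly-A spikes moved in the same direction and by more. The kidney tubule list (3 of 5 fell, adjusted p = 0.17) and the neuronal list (3 of 5 fell, adjusted p = 0.17) were not called. EMX2 and PAX8, transcription factors of the developing kidney, fell 3.80-fold and 1.84-fold, and GAP43 and UCHL1, neuronal proteins, 2.63-fold and 1.55-fold. AQP1 fell 1.69-fold at an adjusted p of 0.040, which none of the 3 normalizations nor any left-out array kept under the threshold. Too few fibroblast, haematopoietic and endothelial markers were measured for a test. VIM fell 1.87-fold. COL3A1 rose 2.12-fold in its brightest probe set, while its others stood at 0.44 and 0.17 log2 units and did not pass. COL1A1 rose 1.47-fold in its brightest probe set with another probe set called in the opposite direction. CORO1A (0.01) and PECAM1 (-0.46) did not pass.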

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

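Of the tests in this part, those on the control probe sets and on the number of calls, including the distances between neighbouring genes, were chosen after those values had been seen, and those on probe sets of 1 gene were written before.

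Among the control probe sets, which lie outside the gene comparison, the poly-A spikes were higher in high glucose by a median of 1.941 log2 units, with all 24 separating the groups, and the ribosomal RNA probe sets by 1.725, with 5 of 6 separating them. Hybridisation or scanning is argued against, because the hybridisation controls had a median log2 difference of -0.339, or 0.015 without high glucose replicate 1, which alone was low, against 1.094 for the spike probe set that differed least. A lower share of messenger RNA in the RNA labelled from the high glucose cells predicts a rise of ribosomal RNA as well as spikes. The median difference of 1.725 goes with it. Single ribosomal probe sets ranged from 0.392 to 2.119, however. The brightest differed least, with 791 and 969 in high and 638 and 697 in low glucose, so this explanation is not settled. A labelling batch or another spike dose cannot be told apart from glucose, since the labels give neither, and the separation in all 24 spike probe sets only restates the pattern.

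The count of called genes, 7049, is large for 2 arrays per group. A signal-dependent scaling difference is argued against as the whole cause, since cyclic loess normalization left 6905 calls, 6730 of them shared with the main calls in the same direction. Cell sublines that differ in copy number cannot be told apart from glucose: of 6 distances along the chromosomes that were computed, fold changes correlated beyond the largest of 100 shuffles at 3 (0.063 for genes 1 apart, 0.037 for 2 and 0.029 for 10) and not at the others (0.027 for 5, 0.015 for 20 and 0.016 for 50), and nearby genes can also share regulation. Medians over windows of 40 neighbouring genes, with no bound set beforehand, went both ways. The highest, 0.4535, lay beyond the highest of 20 shuffles (0.3635), and the lowest, -0.6025, lay within the lowest of them (-0.6085). Replicates that vary less than separate cultures would stay open too, because the SD of log2 differences was 0.269 within groups and 0.711 between them. A difference due to glucose was not tested apart from these and remains open.

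Of 3527 pairs of probe sets that name the same gene and were both called, 15.9% went in opposite directions, which touched 489 of the called genes. Probe sets marked _x_at or _s_at, as matching several transcripts, are not the whole source. Pairs without such a probe set were opposite more often (20.4% against 13.9%, ratio 1.467, 95% bootstrap interval 1.25 to 1.72). Brightness was not matched between these kinds of pair, so the ratio cannot exclude a part for such probe sets. Among pairs with both probe sets above a signal of 200 the opposite share was 12.5%, against 20.6% for dimmer pairs, a ratio of 0.607 (0.518 to 0.704). That ratio lies between the bounds set beforehand, so dim probe sets may account for part of the pattern. Transcript variants of the genes were not tested.

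Among 4236 probe sets that name no gene or several, which the gene comparison leaves out, 1876 were called, 904 higher and 972 lower in high glucose. The largest change among them was 7.79 log2 units in a probe set without a named gene, with 1310 and 1180 in high glucose and 4.5 and 7.01 in low glucose.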

How the results depend on the processing

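The call count of 7049 ranged from 5122 to 7110 over the normalizations, filters, pseudocount, eBayes settings, probe set choices and the replicate block, and from 5925 to 6225 with 1 array left out, where the lone array of a group is assumed to vary like the others. Deviations of same-numbered arrays from their group means had a correlation of -0.0039, which gave no sign that the numbers pair the arrays, and the labels do not settle it. The replicate block gave 6983 calls, 6808 of them shared with the main calls, and changed the call of fatty acid synthesis (adjusted p = 0.044) among lists and of AQP1 and CYBA among named genes. Quantile, median-centring and cyclic loess normalization kept 6484, 5802 and 6730 of the main calls in the same direction. The number of genes tested also differed between settings. With no filter 6836 of 19775 genes were called, with the stricter filter 5940 of 9110, and without _x_at and _s_at probe sets 5122 of 9457. Other definitions gave other counts: 13759 per probe set (6318 higher, 7441 lower), 3683 with a 1.5-fold change added (1325 and 2358), and 2704 with all 4 array ratios at least 1.5-fold and no test (964 and 1740). The number of lists called, 13, ranged from 11 to 16, but was 0 with an estimated correlation and 22 with fry; leaving out arrays gave 11 to 16. With an estimated correlation the test has few residual degrees of freedom by construction. The estimates also lay far above the preset 0.01 for 3 called lists. They were 0.958 for ribosomal proteins, 0.320 for keratinised epithelial and HeLa-type markers and 0.315 for oxidative phosphorylation. For the other called lists they lay between -0.050 (NF-kappaB) and 0.080 (cytosolic heat shock), with -0.019 for the ATF4 list. Other causes were not tested. Reversed values were ATP6AP2 after median centring (0.063), COL1A1 and TKT as means of probe sets (-0.0014 and 0.0055), TKT without _x_at and _s_at probe sets (1.22), PECAM1 without high glucose replicate 2 (0.165, down to -1.08 with other arrays left out), and CORO1A without low glucose replicate 1 (-0.033, up to 0.060 with other arrays left out). For the immediate early list camera's direction turned from up to down with the stricter filter and without _x_at and _s_at probe sets, while its mean shift against other genes stayed positive (0.117 and 0.154, from 0.351). Leaving out genes with opposite probe sets, added after seeing the data, gave 6593 calls and 13 lists. Of 2150 values of 140 named genes under alternatives, 2120 kept direction and side of the threshold. Nearly all of these genes were named for large changes or small p in the same data, so this share does not carry over to all calls. Of all main calls, the mean of probe sets kept 5740 in the same direction and called 90 in the opposite direction. Folds of genes with a group mean near or below the filter signal of 32.9 rest on signals not shown to be above background.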

Other observations

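All 7 lists in this part were chosen after the gene table had been seen, and only the test of the YAP targets without the 5 members seen first, the eighth list tested, was fixed before its result. The BMP list without the 2 members seen first, the ninth, was added after its members had been seen. The poly-A spikes and ribosomal RNA probe sets, higher in high glucose by 1.94 and 1.73 log2 units, moved in the same direction as the lists that rose. Both differences exceed the medians of those lists. Proteasome subunits were higher in high glucose in 18 of 23 measured members and lower in 0, with PSMD12 2.59-fold, PSMD1 2.29-fold and PSMC6 2.05-fold higher (median 0.45, camera adjusted p = 4.4e-08 over 9 lists, adjusted p = 0.23 with an estimated correlation). Ribosome biogenesis factors rose in 18 of 23 and fell in 2, with TSR1 3.99-fold and NOP58 2.21-fold higher (median 0.56, adjusted p = 3.0e-06, adjusted p = 0.12 with an estimated correlation). The list of BMP response genes was prompted by ID1 (6.84-fold higher) and BMP4, whose low glucose mean lay below the filter signal of 32.9. Without these, 9 of 12 members rose and 1 fell, among them SMAD7 (3.90-fold higher), while MSX1 fell by 0.78 log2 units (median 1.07, adjusted p = 4.5e-05, adjusted p = 0.12 with an estimated correlation). With them, 11 of 14 rose (adjusted p = 3.6e-06, adjusted p = 0.12 with an estimated correlation). Chaperonin and prefoldin subunits were called weakly (4 of 12 rose, 1 fell, adjusted p = 0.043, adjusted p = 0.46 with an estimated correlation).

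Aminoacyl-tRNA synthetases went both ways, with 6 of 17 rising and 8 falling (adjusted p = 0.74). SARS1, AARS1, WARS1 and CARS1 were lower in high glucose by 2.99-fold, 2.90-fold, 2.80-fold and 1.86-fold, and RARS1 was 3.73-fold higher. ER-to-Golgi transport genes fell in 13 of 24 and rose in 4 (adjusted p = 0.13), with SEC24D 3.17-fold lower and SAR1B 2.45-fold higher.

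A hypothesis from the largest rises is that targets of YAP and TEAD, which respond to cell density and shape, were higher in high glucose as a group. All 20 measured members gave an adjusted p of 2.2e-04 (adjusted p = 0.12 with an estimated correlation), but 5 of them (CCN1, CCN2, ANKRD1, AMOTL2, MYOF) had prompted the hypothesis. The remaining 15 members had a median of 0.67, with 5 rising, among them CRIM1 (2.70-fold) and TGFB2 (2.88-fold), and 3 falling, among them GADD45A (2.17-fold). Their camera p was 0.0525 (adjusted p = 0.067, adjusted p = 0.26 with an estimated correlation), which missed the bound of 0.05 set beforehand, so the hypothesis was not borne out beyond the genes that prompted it. The miss is narrow, and it does not show that these members were level. Cell density at harvest was not tested.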
